A study of Mus musculus with 8 samples.

How the data were processed

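Polyadenylated RNA was sequenced from cultures of mouse bone marrow stromal cells, the adherent marrow cells that include the precursors of bone-forming osteoblasts. Each genotype had 4 libraries. The cells came from wild-type mice and from mice homozygous for an Lgr6-GFP-ires-CreERT2 allele, a reporter and inducible recombinase cassette at Lgr6, called Lgr6-null in the sample titles; the strain background is given as C57BL/6. Per the labels, cultures near confluence were given osteogenic medium (50 µg/mL ascorbic acid, 4 mM β-glycerophosphate and 10% fetal bovine serum) for 10 days, and libraries came from a stranded mRNA kit read as 100 bp paired ends.

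The submitters' processing notes name HISAT2 2.1.1, HTSeq 0.13.5, DESeq2 and the mouse build GRCm39. The gene annotation, the strand setting of the counting and the handling of reads that match several places are not given in the sources used here. The deposited table holds a signal, normalized counts of 19460 genes in 8 libraries. Within each column 100% of the values were whole multiples of a single step, within a tolerance of 0.01 read, as values are when gene read counts are divided by 1 size factor per library, and whole reads were recovered from them. The lowest total of a gene over the 8 libraries was 11 reads, so genes with fewer are not analysed here. Recovered totals ran from 7629968 to 21135173 reads in genes per library. Symbols, biotypes and chromosomes came from a GENCODE annotation of the earlier build GRCm38, matched by gene identifier: 19361 identifiers matched and 99 did not. Distances between genes were taken from that annotation, and no coordinates are printed.

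Column names carry the genotype and a number (M0 to M3 for wild-type; M0, M2, M3 and M4 for Lgr6-null) that cannot be tied to the replicate numbers of the sample titles, so columns were assigned to genotypes only and are named here by those numbers. The labels do not say whether libraries of a genotype came from separate animals or cultures, so p-values measure the spread between these libraries, whatever its source. Within genotypes, the chi-square of the recovered reads per degree of freedom was at least 8.59, so no library was a copy of another.

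Lgr6-null was compared with wild-type in limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2(normalized count + 1), without covariates. Genes with a normalized count of at least 10 in at least 4 of the 8 libraries were tested, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are Lgr6-null minus wild-type on that scale, which understates the change of low genes. The adjusted p-values of genes come from this limma fit. For a gene without reads in a genotype, the fold was bounded with 3 reads over that genotype's libraries; for 1 to 3 reads, the ratio of read rates is given with its exact 95% binomial interval. Both cover counting error only, and neither was applied to the lists written after values were seen. The Lgr6 level was also tested with a two-sided exact permutation test.

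Before the data were examined, 25 gene lists and 12 lists of cell type or sex markers were written from general knowledge, with the rule for named genes: Lgr6; the 10 largest rises and 10 largest falls among called genes with a mean of at least 50 and no overlap between the genotypes, leaving out symbols of predicted genes; from each list up to 4 called members by smallest p, or the measured member with the smallest p where none was called; and Lgr4, Lgr5, Runx2, Sp7, Alpl, Col1a1, Bglap, Ibsp and Dmp1. Other genes named were chosen after their values were seen. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over 37 lists. camera tests a list against the other genes and fry against no change, so ranges over alternatives hold camera alone. Called members are counted over all genes tested and adjusted over the list alone.

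The tests were tried on simulated counts with 200 changed genes, drawn with the mean gene levels, spread and depths of these libraries. There limma called 44.8% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 98.5% of those changed 4-fold in the right direction, and 9 unchanged genes of 14284 tested. camera called 0 of 37 unchanged lists and called the 1 list that was shifted 1.5-fold. The simulation took no correlation between genes from the libraries, so it cannot show how often camera calls unchanged lists of correlated genes. In the libraries, estimated correlations ran from -0.245 (granulocyte markers) to 0.889 (proliferation genes), with 0.347 for osteoblast genes. Nor does a trial with 200 changed genes cover data in which 3676 genes were called.

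Alternatives set before the data were examined were pseudocounts of 0.5 and 5, no filter, a mean of at least 50, scaling to the same total, quantile normalization, limma without the trend or with robust variances, sample weights, edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on the recovered reads, stricter thresholds, and leaving out each library in turn. Chosen after seeing the data were the column number as a replicate block, the mean of the macrophage markers as a covariate, and scaling to 20 genes shared by mesenchymal cells in general, called pan-mesenchymal genes.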

Results

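RNA of cultures after 10 days of osteogenic differentiation was compared in 8 libraries, 4 from Lgr6-null and 4 from wild-type mice. The comparison asks which genes and signaling pathways go with Lgr6, a receptor of the R-spondins, which strengthen Wnt signaling, while osteoblasts form. Wild-type libraries M0, M1, M2 and M3 held 16870532, 17425324, 18672187 and 12561103 reads in genes, and Lgr6-null libraries M0, M2, M3 and M4 held 18504870, 17419716, 21135173 and 7629968. Col1a1, the main collagen chain of bone, had the most reads in every wild-type library (4.33% to 5.79%), and Lyz2, a lysozyme of macrophages, in every Lgr6-null library (1.65% to 2.44%). The first principal component of the 500 most variable genes, with 74.1% of their variance, separated the genotypes, and the second, with 8.35%, set Lgr6-null library M4, the shallowest, apart.

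Lgr6 itself (ENSMUSG00000042793, chromosome 1) was at 76.2 ± 19.2 normalized counts in Lgr6-null (SD, n = 4) and at 1287 ± 303 in wild-type (SD, n = 4). The Lgr6-null mean was 5.92% of the wild-type mean, a log2 fold change of -4.06 (SE 0.20, limma adjusted p = 2.73e-06), and all 4 Lgr6-null libraries lay below all 4 wild-type libraries. The two-sided exact permutation p was 0.0286, the smallest that 4 against 4 libraries allow. The remaining signal rested on 32 to 139 reads per Lgr6-null library. Of the related R-spondin receptors, Lgr4 fell from 550.3 ± 62.2 to 231 ± 40.5 (log2 fold change -1.26, SE 0.14), and Lgr5 was at 178 ± 99.1 in Lgr6-null and 100.4 ± 36.2 in wild-type without a call (adjusted p = 0.230).

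At a preset correlation between genes, camera called the lists of osteoblast, osteocyte and BMP pathway genes lower and the macrophage markers higher in the Lgr6-null cultures. With an estimated correlation all 4 calls were lost (adjusted p = 0.284, 0.163, 0.163 and 0.552). Of 14294 genes tested, 1855 were higher and 1821 lower in Lgr6-null, 25.7% in all, and 386 and 661 of these changed at least 2-fold. The genotypes did not overlap in 29.1% of tested genes, where chance gives 2.86%. Without Lgr6-null library M4, 1839 were higher and 1769 lower, the highest counts with 1 library left out. The lowest such counts were 1321 higher and 1375 lower. The balance depended on scaling: 2886 were higher and 1281 lower with libraries scaled to the same total, and 609 and 2934 with scaling to pan-mesenchymal genes, which moved the median log2 fold change of all genes from 0.00 to -0.22. With the column number as a replicate block, 937 were higher and 1021 lower, and with the macrophage marker mean as a covariate 407 and 620.

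Osteoblast genes fell broadly. Ibsp, a sialoprotein of bone matrix, went from 288731 ± 38064 in wild-type to 20099 ± 6356 in Lgr6-null (SD, n = 4; log2 fold change -3.89, SE 0.22, limma adjusted p = 5.95e-06), and Col1a1 from 792253 ± 117299 to 129990 ± 10701 (log2 fold change -2.60, SE 0.24). Osteocalcin, Bglap, fell by 4.25 on the log2 scale (SE 0.43), and Alpl, the phosphatase that mineralization needs, fell by 1.92 (SE 0.23). Transcription factors of osteoblast differentiation were lower too: Runx2 at -1.27 (SE 0.22) and Sp7 at -2.08 (SE 0.25). So were the collagen-binding protein Sparc at -1.69 (SE 0.13) and the collagen chain Col5a2 at -1.32 (SE 0.11). Among 24 osteoblast genes measured, 1 rose and 19 fell (the same adjusted over the list alone), with a median log2 fold change of -2.18; the rise was the proteoglycan Ogn (0.89). camera gave an adjusted p of 3.68e-11 (2.19e-32 to 0.284 over camera's alternatives, and adjusted p = 0.000174 with fry), with adjusted p = 0.284 with an estimated correlation. In the same libraries the mean log2 level of the macrophage markers was 13.19 to 13.77 in Lgr6-null and 12.83 to 13.03 in wild-type. Bglap has near-identical neighbouring copies, so its own level is uncertain.

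**Figure D1:**
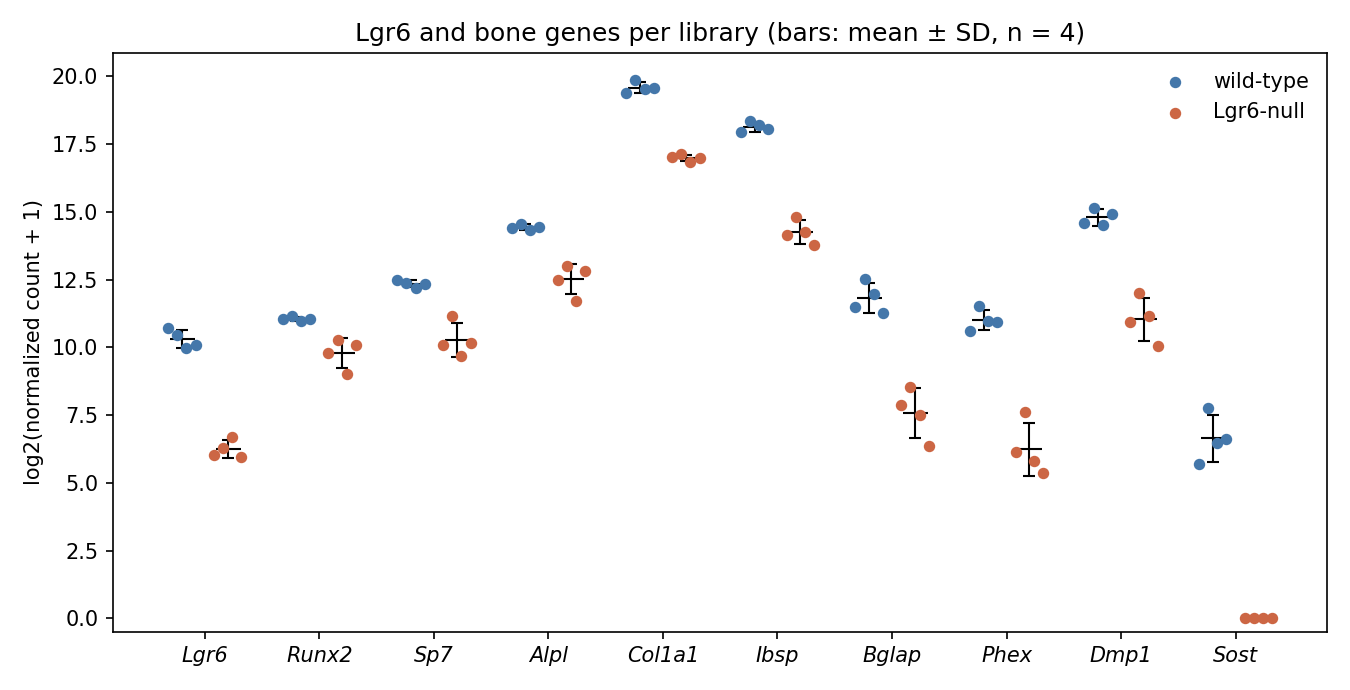
Level of Lgr6 and 9 bone genes in each library as log2(normalized count + 1), for wild-type and Lgr6-null libraries, with bars at the mean and SD of 4 libraries. All Lgr6-null libraries lie below all wild-type libraries in each gene; Ibsp, for example, lies between 17.93 and 18.36 in wild-type and between 13.76 and 14.82 in Lgr6-null.

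Osteocyte genes, of the cells embedded in bone, fell alongside. Sost, which encodes the secreted Wnt antagonist sclerostin, had 463 reads over the wild-type libraries and 0 over the Lgr6-null libraries, at least 161-fold lower with 3 reads over the genotype as the floor. Phex, which acts in phosphate handling, fell from 2113 ± 576 to 90.1 ± 71.6 (log2 fold change -4.78, SE 0.42), and the matrix phosphoprotein Dmp1 from 28861 ± 6189 to 2348 ± 1280.0 (log2 fold change -3.76, SE 0.34). The chemokine receptor Ackr3 fell by 2.65 (SE 0.27). Among 11 genes measured, 0 rose and 10 fell (the same adjusted over the list alone), with a median of -1.07, the same with Sost at its bound. camera gave an adjusted p of 4.31e-08 (1.10e-09 to 0.163 over camera's alternatives, and adjusted p = 9.77e-05 with fry), with adjusted p = 0.163 with an estimated correlation.

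Among Wnt target genes, the largest falls were in inhibitors of the pathway. The Wnt deacylase Notum fell from 297 ± 64.1 to 24.8 ± 10.8 (log2 fold change -3.59, SE 0.28), the secreted antagonist Wif1 from 807 ± 197 to 48.8 ± 21.9 (log2 fold change -4.11, SE 0.35), and Rnf43, a ubiquitin ligase that removes Wnt receptors, fell by 2.61 (SE 0.31). The antagonist Dkk1 had 171 reads in wild-type and 1 in Lgr6-null, a ratio of 179 with a counting interval from 31.7 to 7108. Axin2, a target widely used as a readout of the pathway, was at 0.36 without a call. Among 15 genes measured, 1 rose and 6 fell (the same adjusted over the list alone), with a median of -0.39; Nkd1, another inhibitor, was the rise (1.00). The camera adjusted p was 0.0284 (0.000551 to 0.616 over camera's alternatives, and adjusted p = 0.0238 with fry). The call was lost with an estimated correlation (adjusted p = 0.616), with sample weights (adjusted p = 0.0737), without wild-type library M0 (adjusted p = 0.0708), without Lgr6-null library M3 (adjusted p = 0.0895) and with the macrophage covariate (adjusted p = 0.602), where the median was 0.040.

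Wnt ligands, receptors and secreted inhibitors went both ways. The ligand Wnt2b (1.88) and the inhibitor Dkk2 (1.83) rose, while the receptors Fzd9 (-1.94, SE 0.27) and Fzd5 (-1.34, SE 0.19) and Lrp4, a receptor that binds sclerostin, (-1.19, SE 0.18) fell, as did Lgr4. Among 35 measured, 6 rose and 4 fell (the same adjusted over the list alone), and camera gave an adjusted p of 0.958.

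Most measured genes of the BMP pathway, which drives osteoblast differentiation, fell. Id3, a direct target of BMP signaling, went from 4483 ± 53.2 to 1812 ± 123 (log2 fold change -1.31, SE 0.06, limma adjusted p = 2.36e-06), and its relative Id2 fell by 1.17 (SE 0.13). The signal transducer Smad9 fell by 2.07 (SE 0.19) and Bmp3 fell by 2.72 (SE 0.27). The inhibitors Nog (-2.09) and Bambi (-2.57) fell as well, and the ligand Bmp6 rose (3.29). Among 25 genes measured, 1 rose and 15 fell (1 and 16 adjusted over the list alone), with a median of -0.77. camera gave an adjusted p of 4.31e-08 (1.17e-11 to 0.163 over camera's alternatives, and adjusted p = 9.77e-05 with fry), with adjusted p = 0.163 with an estimated correlation.

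The TGF-β, Hedgehog, Notch, ERK and immediate early lists were not called by camera at the preset correlation. In the TGF-β list of 19 genes, 7 rose and 2 fell (7 and 4 adjusted over the list alone): the receptor Tgfbr2 (0.71), the matricellular protein Ccn2 (0.57) and smooth muscle actin Acta2 (1.10) were among the rises and the latent TGF-β binding protein Ltbp1 (-1.36) among the falls (camera adjusted p = 0.160). In the Hedgehog list of 7 genes, 0 rose and 3 fell (the same adjusted over the list alone), namely the pathway targets Gli1 (-2.33) and Ptch1 (-1.43) and the transducer Smo (-0.47), with a camera adjusted p of 0.0957; Smo was not called with libraries scaled to the same total and was at 0.080 with the macrophage covariate. Among 9 Notch pathway genes, 1 rose and 0 fell (the same adjusted over the list alone), with the receptor Notch1 higher by 0.84 (SE 0.08; camera adjusted p = 0.129). In the list of 27 ERK feedback and growth factor genes, 6 rose and 3 fell (7 and 5 adjusted over the list alone), with the ligand Ereg (1.03), the ERK phosphatase Dusp6 (0.76) and Etv1 (0.67) higher and the receptor Fgfr3 lower (-2.32; camera adjusted p = 0.363). Of 18 immediate early genes, which respond to stimuli within minutes, 4 rose and 3 fell (4 and 4 adjusted over the list alone), with Ier2 higher (0.53) and Klf4 (-1.22), Atf3 (-0.84) and Fosl1 (-0.79) lower (camera adjusted p = 0.805). fry called the TGF-β (adjusted p = 0.0429), Hedgehog (adjusted p = 0.0130), Notch (adjusted p = 0.0120) and ERK (adjusted p = 0.0481) lists, the macrophage covariate the Notch list (adjusted p = 0.0210) and the fit without Lgr6-null library M2 the Hedgehog list (adjusted p = 0.0469).

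Matrix genes parted in direction. The collagen chaperone Serpinh1 fell from 27686 ± 1822 to 11469 ± 742 (log2 fold change -1.27, SE 0.08), the collagen prolyl hydroxylase P3h1 fell by 1.07 (SE 0.06), the crosslinking enzyme Loxl4 fell by 2.81 (SE 0.22) and the collagen chain Col11a2 fell by 3.78 (SE 0.30), while elastin, Eln (3.22), and the collagen chains Col5a3 (1.08) and Col3a1 (0.93) rose. Among 26 fibrillar collagen and crosslinking genes, 8 rose and 9 fell (9 and 9 adjusted over the list alone). The camera adjusted p was 0.530 in the downward direction, with a mean of -0.21 and a median of 0.12, and the list was called with DESeq2 (adjusted p = 0.00564) and fry (adjusted p = 0.0467). Among 22 matrix proteases and their inhibitors, 7 rose and 8 fell (10 and 9 adjusted over the list alone): Mmp13, a collagenase of bone, fell by 2.18 (SE 0.22), Mmp16 fell by 1.30 and Adamts9 fell by 1.31, and Adamts5 rose (1.27). Their camera adjusted p was 0.842 in the downward direction, with a mean of -0.04 and a median of 0.02.

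Several hypoxia targets fell. Ndrg1 fell by 2.22 (SE 0.19), the oxygen sensor Egln3 fell by 1.76 (SE 0.32), and the collagen prolyl hydroxylase subunits P4ha1 and P4ha2 were at -1.27 (SE 0.17) and -1.08 (SE 0.08). Among 14 hypoxia targets, 1 rose and 8 fell (the same adjusted over the list alone), with a median of -0.61, and the rise was Adm (0.59). camera gave an adjusted p of 0.00387 (6.25e-05 to 0.511 over camera's alternatives, and adjusted p = 0.00395 with fry), with adjusted p = 0.511 with an estimated correlation. In the list of the unfolded protein response and ATF4 targets, 1 rose and 8 fell (the same adjusted over the list alone) of 23, with a median of -0.31. The lipoprotein receptor Vldlr (-2.27), the transcription factor Atf4 (-0.36) and the folate enzyme Mthfd2 (-0.49) were lower, the cystine transporter Slc7a11 was higher (1.81), and the chaperone Hspa5, a main target of the unfolded protein response, was at -0.06 without a call. Its camera adjusted p was 0.00808 (0.00172 to 0.163 over camera's alternatives, and adjusted p = 0.000800 with fry), with adjusted p = 0.163 with an estimated correlation and adjusted p = 0.141 with the macrophage covariate.

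Lists of energy metabolism, division and protein synthesis were not called by camera at the preset correlation. Among 21 glycolysis genes, 1 rose and 6 fell (1 and 7 adjusted over the list alone), with Ldha (-0.51), Eno1 (-0.47) and Hk1 (-0.35) lower and Ldhb higher (0.68; camera adjusted p = 0.0957). Among 22 cholesterol synthesis genes, 1 rose and 6 fell (1 and 7 adjusted over the list alone), with Sqle (-0.41) and Lss (-0.27) lower and Dhcr7 higher (0.43; camera adjusted p = 0.104). Of 24 nuclear genes of the respiratory chain, 1 rose and 2 fell (1 and 0 adjusted over the list alone): Sdhb (0.35), and Cox6a1 (-0.18) and Ndufa1 (-0.27), with a camera adjusted p of 0.805. Of 10 mitochondrially encoded genes, 0 rose and 0 fell (the same adjusted over the list alone), and mt-Co3 had the smallest p (log2 fold change 2.02, limma adjusted p = 0.0647; camera adjusted p = 0.138). Of 26 proliferation genes, 0 rose and 1 fell (0 and 0 adjusted over the list alone), namely the replication helicase subunit Mcm6 (-0.70; camera adjusted p = 0.842). Of 28 ribosomal protein genes, 0 rose and 1 fell (0 and 0 adjusted over the list alone), namely Rplp0 (-0.25; camera adjusted p = 0.761, with a mean of 0.00704 and a median of -0.0292). Of 17 p53 targets and senescence genes, 4 rose and 1 fell (the same adjusted over the list alone), with the cell cycle inhibitor Cdkn2a (0.58), Ccng1 (0.48) and Sesn1 (0.55) higher and Igfbp3 lower (-1.20; camera adjusted p = 0.0699). Alternatives called the p53 list 6 times, glycolysis 5 times, cholesterol synthesis 3 times, and proliferation and the mitochondrially encoded genes 1 time each, the latter without Lgr6-null library M4 (adjusted p = 0.0352). With the macrophage covariate, whose values do not overlap between the genotypes, medians were -0.61 for glycolysis (adjusted p = 8.62e-11), -0.71 for proliferation (adjusted p = 2.35e-08), -0.37 for cholesterol synthesis (adjusted p = 3.42e-05) and 0.49 for the p53 list (adjusted p = 0.000104).

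Most markers of macrophages and monocytes rose. The complement component C1qa went from 15151 ± 915 in wild-type to 29670 ± 5970.1 in Lgr6-null (log2 fold change 0.95, SE 0.13, limma adjusted p = 0.000836), the mannose receptor Mrc1 rose by 1.04 (SE 0.16), the growth factor receptor Csf1r by 0.70 (SE 0.13) and Laptm5 by 0.61 (SE 0.13). Lyz2, the most abundant of these markers, was at 168677 ± 14002 in wild-type and 300686 ± 68566 in Lgr6-null. Among 18 markers, 12 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 0.56. camera gave an adjusted p of 1.57e-05 (4.04e-07 to 0.552 over camera's alternatives, the highest with an estimated correlation, and adjusted p = 0.0295 with fry), leaving aside the macrophage covariate, which is the mean of these markers and removes their difference by construction.

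**Figure D2:**
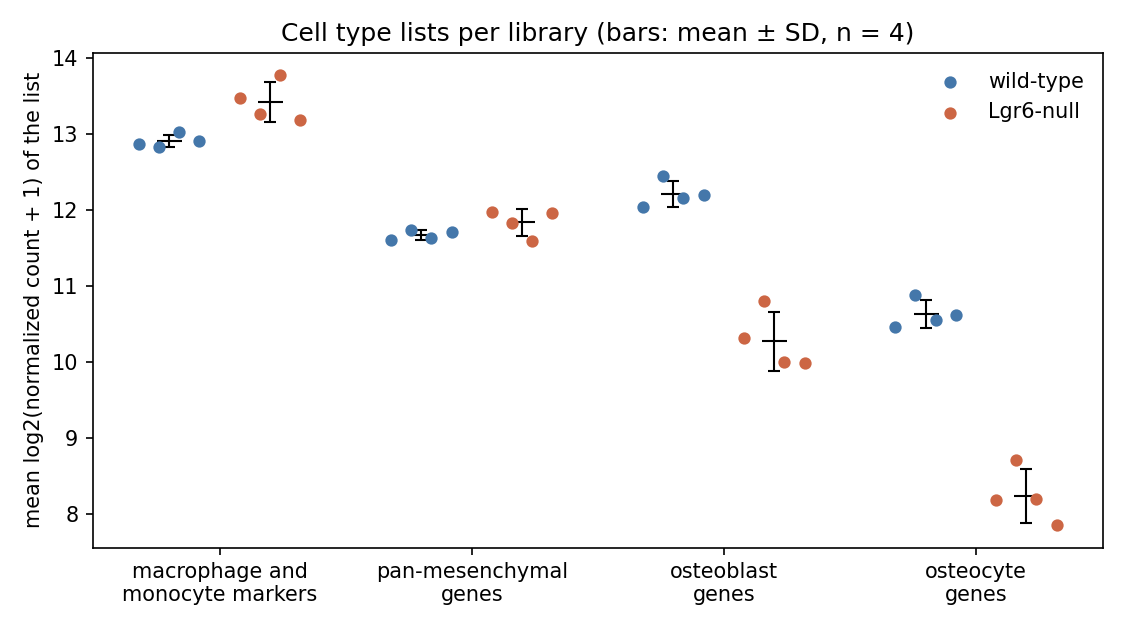
Mean log2(normalized count + 1) of the macrophage, pan-mesenchymal, osteoblast and osteocyte lists in each library, for wild-type and Lgr6-null libraries, with bars at the mean and SD of 4 libraries. Osteoblast genes lie between 12.05 and 12.45 in wild-type and between 9.98 and 10.81 in Lgr6-null, and pan-mesenchymal genes between 11.60 and 11.74 and between 11.59 and 11.97.

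The inflammatory and interferon lists were called higher by camera at the preset correlation, and both calls were lost under other settings. The adhesion molecule Vcam1 rose from 606 ± 44.8 to 1250.0 ± 133 (log2 fold change 1.04, SE 0.09) and the acute phase protein Saa3 by 1.95 (SE 0.37), and the alarmin Il33 had 2 reads in wild-type and 202 in Lgr6-null, a ratio of 96.5 with a counting interval from 26.4 to 803. Ptgs2, a prostaglandin synthase, fell by 1.33 (SE 0.07). Among 19 inflammatory cytokines and chemokines, 9 rose and 2 fell (10 and 2 adjusted over the list alone), with a median of 0.70 and a camera adjusted p of 0.00387 (1.97e-06 to 0.552 over camera's alternatives). The call was lost with an estimated correlation (adjusted p = 0.552), with fry (adjusted p = 0.0504) and with the macrophage covariate (adjusted p = 0.295). Among 26 interferon response genes, 4 rose and 0 fell (3 and 0 adjusted over the list alone): the RNA sensor Ddx58 (0.45), Oas1a (0.73), Ifi27 (0.34) and the transcription factor Irf9 (0.34), with a median of 0.35 and a camera adjusted p of 0.00924 (7.03e-06 to 0.752 over camera's alternatives). That call was lost with an estimated correlation (adjusted p = 0.752), without wild-type library M1 (adjusted p = 0.105), with scaling to the same total (adjusted p = 0.0553), with DESeq2 (adjusted p = 0.0908), with fry (adjusted p = 0.268) and with the macrophage covariate (adjusted p = 0.623).

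Markers of other mesenchymal and bone cells went in different directions. Among 7 chondrocyte markers, 0 rose and 3 fell (0 and 4 adjusted over the list alone), with a median of -0.84: the cartilage proteoglycan Acan went from 79.5 ± 19.1 to 1.37 ± 1.27 (log2 fold change -5.23, SE 0.42), and the transcription factor Sox6 (-2.28) and the matrix protein Comp (-1.93) fell. The camera adjusted p was 0.0135 (0.00425 to 0.214 over camera's alternatives, and adjusted p = 9.77e-05 with fry), and the call was lost with an estimated correlation (adjusted p = 0.214), with a mean of at least 50 (adjusted p = 0.181) and with the macrophage covariate (adjusted p = 0.0554). Of 8 osteoclast markers, 1 rose and 3 fell (1 and 4 adjusted over the list alone), with Acp5 (-1.12), Ctsk (-0.68) and Atp6v0d2 (-1.73) lower and Mmp9 higher (1.37; camera adjusted p = 0.160). Of 9 adipocyte markers, 0 rose and 3 fell (1 and 4 adjusted over the list alone), with Scd1 (-1.20), Lpl (-1.35) and Fabp4 (-1.01) lower (camera adjusted p = 0.118). Of 10 smooth muscle and pericyte markers, 4 rose and 1 fell (the same adjusted over the list alone), with Acta2, Myh11 (1.46) and Cnn1 (0.87) higher and the proteoglycan Cspg4 lower (-2.58; camera adjusted p = 0.0808). Of 18 stromal progenitor genes, 3 rose and 3 fell (3 and 4 adjusted over the list alone), with Pdgfrb (0.57) higher and Nt5e (-1.44), Lepr (-0.93) and Cd44 (-0.37) lower; camera gave an adjusted p of 0.914 in the downward direction, with a mean of 0.10 and a median of 0.01. Alternatives called the smooth muscle list 4 times, the adipocyte list 2 times and the osteoclast list 1 time, with fry (adjusted p = 0.0110).

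Few markers of blood and vessel cells were high enough to test. Among 6 endothelial markers, 2 rose and 1 fell (the same adjusted over the list alone), with the receptors Tie1 (2.42) and Ptprb (1.54) higher and Kdr (-1.30) lower; camera gave an adjusted p of 0.904 in the upward direction, with a mean of 0.26 and a median of -0.22. Cd79b (1.11) and Blnk (0.45) were called among 3 B cell markers, where 2 rose and 0 fell (the same adjusted over the list alone) with a camera adjusted p of 0.292. Trbc2 (1.27) and Il7r (-1.52) were called among 3 T and NK cell markers, where 1 rose and 1 fell (the same adjusted over the list alone) with a camera adjusted p of 0.855. Pf4 (0.85) and Ppbp (2.32), of platelets, were called among 3 erythroid and megakaryocyte markers, where 2 rose and 0 fell (the same adjusted over the list alone) with a camera adjusted p of 0.104. Csf3r (0.68) was called among 3 granulocyte markers, where 1 rose and 0 fell (2 and 0 adjusted over the list alone) with a camera adjusted p of 0.129. Of 3 skeletal muscle markers, 0 rose and 0 fell (the same adjusted over the list alone), with Acta1 at 1.34 (limma adjusted p = 0.0830; camera adjusted p = 0.752). Of 4 Y-linked genes, 0 rose and 0 fell (the same adjusted over the list alone), with Kdm5d at 0.09 (limma adjusted p = 0.540; camera adjusted p = 0.932). Scaling to pan-mesenchymal genes and fry called the erythroid and megakaryocyte list (adjusted p = 0.00951 and adjusted p = 0.0493) and the granulocyte list (adjusted p = 0.0481 and adjusted p = 0.00164).

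**Figure D3:**
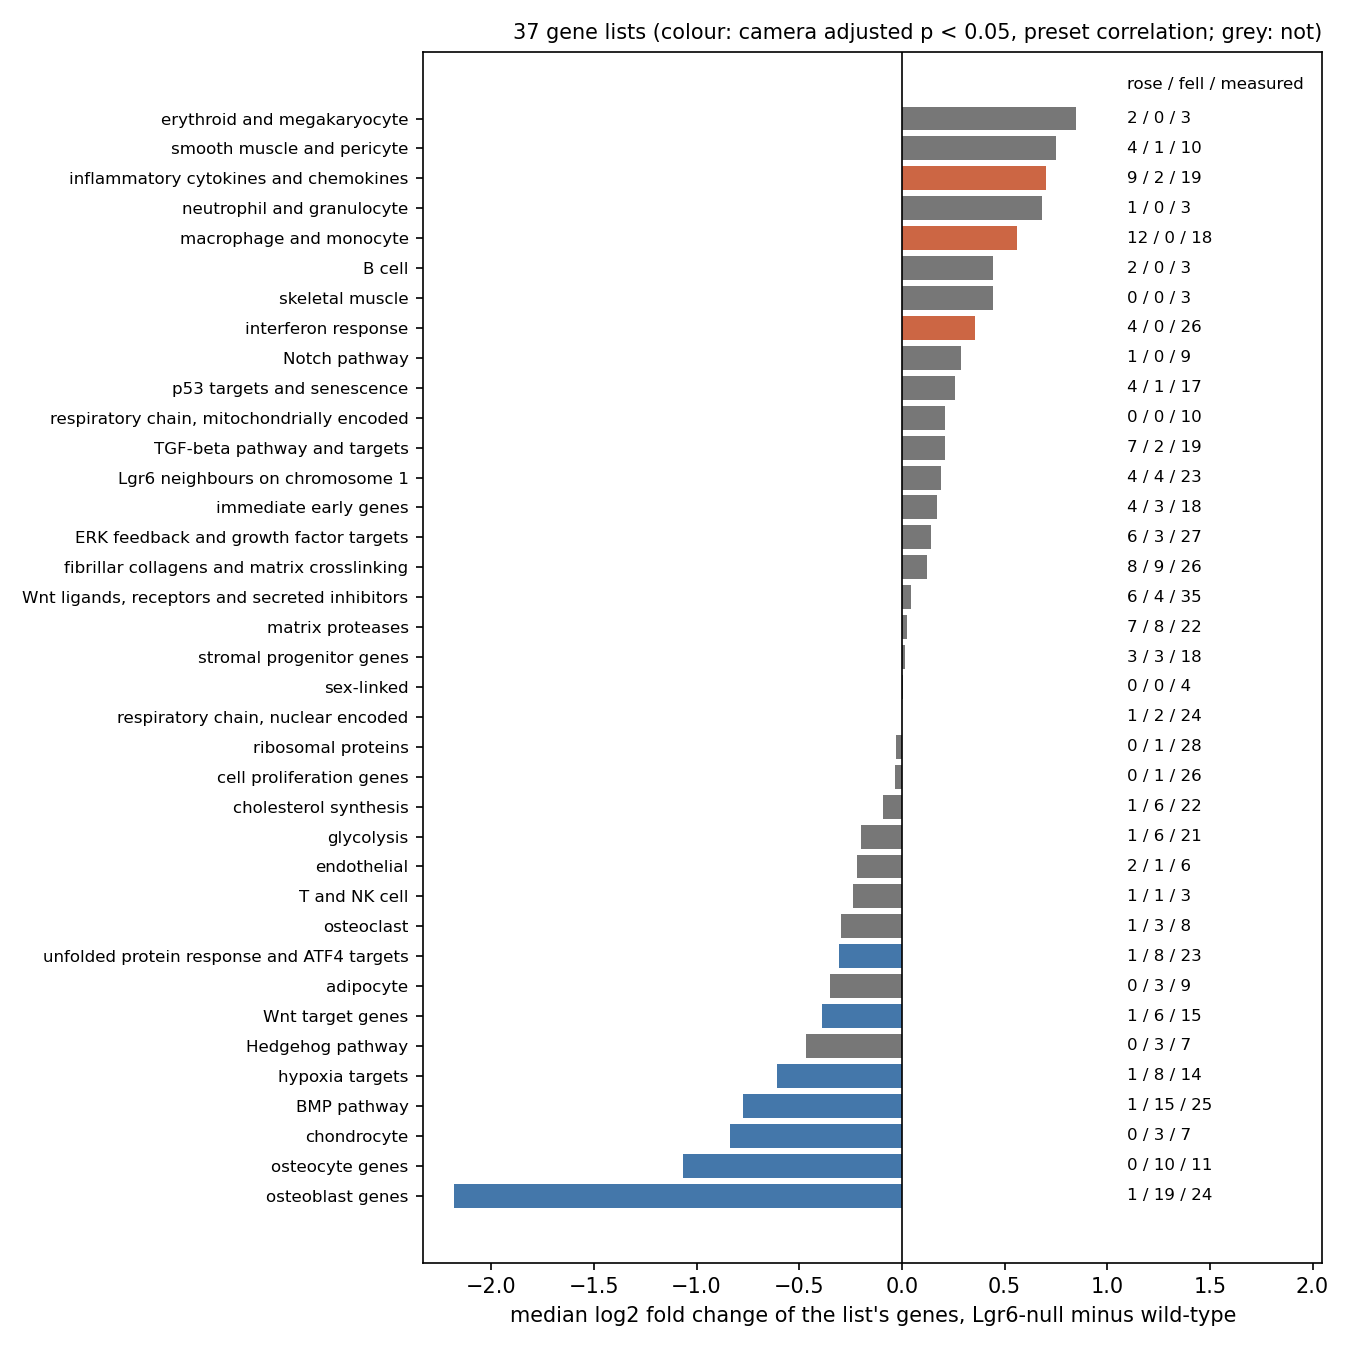
Median log2 fold change (Lgr6-null minus wild-type) of the tested members of 37 lists, with the numbers that rose, fell and were measured beside each bar. Blue bars are lists called lower and orange bars lists called higher by camera at the preset correlation, and grey bars are lists not called; the osteoblast list is lowest at -2.18.

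Several of the largest changes came close to all or none. Eno1b, an enolase gene nearly identical to Eno1, was at 1.68 ± 0.802 in wild-type and 1624 ± 362 in Lgr6-null (SD, n = 4; log2 fold change 9.26, limma adjusted p = 3.95e-08). Ifi202b, of a family of interferon-inducible genes, had 2 reads in wild-type and 2822 in Lgr6-null, a ratio of 1349 with a counting interval from 373 to 11141. The pseudogene Nudc-ps1 had 1 read against 802, a ratio of 767 with an interval from 137 to 30312. Their expressed relatives Eno1 and Nudc were at 8868 and 1233 in Lgr6-null and 12135 and 1314 in wild-type, and reads that match both members of such a pair leave these values uncertain. The protease cathepsin E, Ctse, rose from 19.1 ± 2.40 to 1194 ± 256 (log2 fold change 5.88, SE 0.17), and Ptprv from 72.3 ± 11.9 to 2671 ± 383 (log2 fold change 5.19, SE 0.13). The other large rises were Gdpd3 (4.62), BC002163 (4.54), the peptide transporter Slc15a2 (3.86), the chemokine Ccl24 (3.63) and the protease inhibitor Serpina3n (3.48).

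On the falling side, Trim12a had 530 reads in wild-type and 1 in Lgr6-null, a ratio of 555 with a counting interval from 99.1 to 21944, and its relative Trim30d fell by 4.89 (SE 0.37). Padi4, which converts arginine in proteins to citrulline, went from 117 ± 18.3 to 1.16 ± 1.44 (log2 fold change -6.02), the neuropeptide galanin, Gal, fell by 5.80 (SE 0.51), and the carbonic anhydrase Car3 went from 3473 ± 1217 to 108 ± 46.6 (log2 fold change -5.02). The receptor phosphatase Ptprz1 fell by 5.31, the secreted proteoglycan Esm1 fell by 5.37, AU021092 fell by 5.22 and the sarcoglycan Sgca fell by 4.99. Sost was also among the 10 largest falls.

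Of 23 tested neighbours of Lgr6 on chromosome 1, 4 rose and 4 fell (8 and 5 adjusted over the list alone). Ptprv, Csrp1 (1.19, SE 0.09) and Arl8a (0.38, SE 0.05) were higher, and the collagen-binding proteoglycan Fmod fell from 11275 ± 621 to 3291 ± 1001.2 (log2 fold change -1.84, SE 0.22). The camera adjusted p was 0.238 (0.00564 to 0.552 over camera's alternatives), with calls in DESeq2 (adjusted p = 0.00564) and fry (adjusted p = 4.12e-05).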

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

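Tests chosen only after the result was seen were the scaling test of the osteoblast genes, the count of higher genes above every macrophage marker, the 2-fold calls near and farther from Lgr6, and the tests of nearly absent genes with their definition. The division of the libraries by genotype stood apart from their other divisions. Of the 35 splits of the 8 libraries into 4 and 4, 1, the real split, gave as many genes in its larger direction. This held for higher and for lower genes alike (1 of 35 each), and the highest other split gave 6 genes against 1855 and 1821. Since the real split always counts, 1 of 35 is the smallest share possible. The splits cannot tell the genotype from a difference between animals or cultures, whose number the labels do not give. Of the 5 sex-linked genes, 0 separated the genotypes, which alone would not exclude an unequal mix of sexes. In every library the Y-linked genes lay between 441 and 1633 normalized counts and Xist at 12.5 or below, the pattern of male cells. These values argue against a difference in sex as a source of the calls.

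The genes higher in Lgr6-null may in part reflect RNA of more macrophages in those cultures: within genotypes, they followed the macrophage marker mean with a median correlation of 0.455 against 0.0289 for genes not called, a difference of 0.426 (exact one-sided permutation p = 0.00694 over 576 permutations). The median correlation of lower genes was -0.277, for which no test was run. Of the higher genes, 127 of 1843 outside the marker list (6.89%) had a 95% interval above 1.04, the largest log2 rise of a marker, which excludes nothing, since it takes the largest rises alone and assumes an unchanged macrophage profile. None of the 18 markers is in another list (0 of 18), and the most abundant, Lyz2, was at 300686 in Lgr6-null and 168677 in wild-type. An effect of Lgr6 loss on the number or state of macrophages stays open, as does expression of these genes in the stromal cells themselves.

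The fall of osteoblast genes was weighed against a lower share of stromal cells and against scaling. Pan-mesenchymal genes, which a lower share would lower alike, had a median of 0.11 with 7 of 19 higher and 4 lower. The osteoblast median lay -2.29 from it (95% bootstrap interval -3.06 to -1.49, 10000 draws of genes). That interval draws genes as if independent and holds no spread between libraries. Per library, the osteoblast mean log2 level was 9.98 to 10.81 in Lgr6-null and 12.05 to 12.45 in wild-type. The pan-mesenchymal mean was 11.59 to 11.97 in Lgr6-null and 11.60 to 11.74 in wild-type. These library levels argue against a lower share as the whole cause, although 11 of the 20 pan-mesenchymal genes are in other lists. Scaling to the same total, by quantiles or to pan-mesenchymal genes left the osteoblast median at -1.65 or lower, with the call of camera at the preset correlation kept. The kept call says little about scaling, since camera compares a list with the other genes and a factor per library moves both alike. Scaling to the same total and to pan-mesenchymal genes put the median of all genes at 0.09 and -0.22, so larger shifts were not tried. With an estimated correlation camera's call was lost (adjusted p = 0.284). An effect of the Lgr6 genotype on osteoblast differentiation stays open, as do differences between the animals or cultures in age, plating or marrow content; none of these was tested.

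Genes nearly absent in 1 genotype (a mean of at most 2 there and at least 50 in the other) numbered 14, with 9 higher in Lgr6-null, and 2-fold calls were frequent on part of chromosome 1. Of the nearly absent genes, 0 lay within 10 Mb of Lgr6 and 13 on other chromosomes. DNA of the stem cell strain in that stretch thus cannot account for them through variants in the genes themselves. An effect of such DNA on genes elsewhere was not tested. The remaining 1, Ifi202b, lay on chromosome 1 farther from Lgr6, so carried-along DNA stays open for it. Sequence variants between the mouse lines elsewhere in the genome stay open too. With the nearly absent genes left out, 136 calls of at least 3 log2 units held 8.09% pseudogenes and other calls 1.05% (one-sided Fisher's exact test, odds ratio 8.30, p = 8.62e-07). That comparison was not matched for gene level, and 55 of 582 tested pseudogenes were called in all, so it cannot decide for such variants. Within 10 Mb of Lgr6, 33.0% of genes were called against 25.7% of other genes (one-sided Fisher's exact p = 0.0506), a p just above the threshold that leaves flanking DNA open there, and 15.2% were called 2-fold against 7.07% on other chromosomes (p = 0.00241, exact). From 10 to 50 Mb away, 2-fold calls made up 13.4% (one-sided Fisher's exact p = 1.76e-05), and farther out 7.88% (p = 0.303, exact), so carried-along DNA over a longer stretch is a candidate explanation for calls there. Neither reads shared with pseudogenes' parents nor an effect of Lgr6 itself on these genes was tested.

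A single library stood apart from the other 3 of its genotype in 25 of 292 groups checked, by the gap to the nearest library divided by the range at the 5% critical value of Dixon's test; chance picks about 1 in 20. Where 1 library alone held reads, the ratio was 1: wild-type M0 for Nudc-ps1 and Il33, and Lgr6-null M4 for Trim12a and M2 for Dkk1. Wild-type M2 lay above the other 3 in Gdpd3 (0.944) and Acan (0.851). Wild-type M0 lay below the other 3 in Serpina3n (0.866) and Mcm6 (0.832). Lgr6-null M4 lay below the other 3 in Esm1 (0.862), Lpl (0.860) and the number of genes with a read (0.930). Lgr6-null M2 lay above the other 3 in Ptprz1 (0.903), Ackr3 (0.842) and Loxl4 (0.980). Wild-type M1 lay above the other 3 in Lrp4 (0.870). Lgr6-null M3 lay above the other 3 in Id2 (0.863), Cox6a1 (0.859) and Ndufa1 (0.843). Lgr6-null M2 lay below the other 3 in Tgfbr2 (0.892) and the first principal component (0.901). Wild-type M2 lay below the other 3 in Ptgs2 (0.941). Lgr6-null M3 lay below the other 3 in Fmod (0.855). Lgr6-null M0 lay below the other 3 in Ctsk (0.830). Wild-type M0 lay above the other 3 in Ptprb (0.893). Wild-type M1 lay below the other 3 in Lgr5 (0.930).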

How the results depend on the processing

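Chosen after seeing the data were the replicate block by column number, the macrophage covariate and the scaling to pan-mesenchymal genes. Lgr6 kept its call under each alternative, with log2 fold changes from -4.39 to -3.92. Against 1855 higher and 1821 lower genes, the counts were 2886 higher with scaling to the same total, 609 and 2934 with scaling to pan-mesenchymal genes, 386 and 661 with a 2-fold minimum and 872 and 1035 at an adjusted p under 0.01. With the column number as a replicate block they were 937 and 1021. The planned block by the replicate number of the titles was not run, since columns cannot be tied to titles. Deviations of libraries with the same column number correlated by -0.01, -0.12 and 0.03. For libraries with different numbers this ran from -0.11 to 0.13. The numbers thus gave no sign of pairing, which 3 pairs cannot exclude. With the macrophage covariate, whose values do not overlap between the genotypes, the counts were 407 and 620. Smo reversed there (0.080), and the cause was not tested. The macrophage list was at -0.038 there, near 0 by construction, since the covariate is the mean of its markers. Leaving out 1 library gave 1321 to 1839 higher and 1375 to 1769 lower genes. Of 3046 values of 139 named genes under the alternatives, 2832 were counted as unchanged, 207 lost the call and 6 gained it. Unchanged means a call kept in the same direction, or no call in either fit, whatever the direction. Of 882 values of 37 lists, 820 were unchanged in that sense and 37 gained the call. Another 24 lost the call, among them 10 of 10 camera calls with an estimated correlation. With a mean of at least 50, lists left with fewer than 3 genes gave no value. Lgr6-null library M4, at 7629968 reads, limits the depth at which low genes can be compared.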

Other observations

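The lists of this part were written after values were seen, so their tests are not independent of the data; their p-values were adjusted over these lists and the pan-mesenchymal list. A list of retinoid signaling genes was not called. In it, the retinoic acid carrier Crabp2 (2.37) and the retinoic acid-producing enzyme Aldh1a2 (2.28, from 829 to 3882) were higher. So were the retinol transporter Stra6 (2.24), the receptors Rarb (1.34) and Rxra (0.16), and the retinoic acid-degrading enzyme Cyp26a1 (4.06). Rbp4 was lower (-2.48). Mean normalized counts were low for Cyp26a1 (0.469 in wild-type and 22.7 in Lgr6-null), Stra6 (6.52 and 33.2) and Rarb (9.39 and 25.4). Cyp26a1 thus lay near the floor in wild-type, and its fold is given without a read ratio or counting interval. Of 16 genes measured, 7 rose and 1 fell, also adjusted over the list alone, and 8 did not pass, with a median of 0.10, a limma camera adjusted p of 0.0886, and adjusted p = 0.198 with an estimated correlation. With scaling to pan-mesenchymal genes 6 rose and 2 fell, and the signs of the median (-0.12) and of Rxra changed; Rxra was not called there or with quantile normalization.

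Elastic fibre genes parted: Eln (3.22), Fbln1 (2.50), Mfap5 (1.58), Fbln2 (1.25), Fbn1 (0.96), Loxl1 (0.95) and Fbln5 (0.62) rose, and the crosslinking enzyme Lox (-0.69), Efemp2 (-0.58) and Emilin1 (-0.56) fell, 7 and 3 of 16 measured (8 and 3 adjusted over the list alone). The elastic fibre list had adjusted p = 0.167 in limma's camera. With scaling to pan-mesenchymal genes 7 rose and 5 fell, with a median of 0.19 against 0.41, and Fbln5 was not called. Of 15 basement membrane genes, 5 rose and 3 fell (7 and 3 adjusted over the list alone): the laminin chains Lama5 (1.77), Lamb1 (0.57) and Lamc1 (0.53), nidogen Nid1 (1.48) and collagen Col4a1 (1.36) were higher, and Agrn (-0.68), Lamb2 (-0.51) and Hspg2 (-0.33) lower. Hspg2 was not called with scaling to the same total. Scaling to pan-mesenchymal genes gave 5 rises and 5 falls, with a median of 0.12 against 0.34, and Lamc1 was not called. Their list had adjusted p = 0.167 in limma's camera.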
